A study of Homo sapiens with 18 samples.

How the data were processed

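RNA of the neuroblastoma lines IMR-32 and SK-N-SH, treated for 24 h with DMSO, withaferin A (WA) or withanone (WN), both at 1 µM, was measured on 18 Illumina HumanHT-12 v4 arrays, with 3 biological replicates in each of 6 groups per the labels. The deposited table of non-normalized values holds, per the file headers, 1 signal and 1 detection p-value for each of 47224 probes on each array. The signal is a bead-summarised intensity on a linear scale, deposited without normalization between arrays. The detection p-value, so named per the file headers, was taken to compare a probe with the negative control beads of its array. The deposited series matrix holds quantile-normalized log2 values, made with limma per the submitters' processing notes, and the limma version and the steps before it are not given in the sources used here. How the series matrix was scaled or centred before deposition is unknown, its median value was 6.87, and the values of each array there correlated with its signals at r between 0.995 and 1.000, higher than with any other array for 18 of 18 arrays. Scanner settings and the chips that carried the arrays are not given in the sources used here.

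After 2 probes with 3 missing values were left out, 47222 probes were normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp background correction from the detection p-values, offset 16, quantile normalization and log2), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A probe was kept if its detection p was under 0.01 on at least 3 of 18 arrays, which left 23320 probes. Genes were named from a table of the probes of this platform, with symbols brought up to date through the Entrez identifiers for 30068 of 30115 listed probes. Of the probes analysed 30107 had 1 symbol, 8 had several and 17107 were unnamed here, and these last 2 kinds were not used for genes. Each gene was represented by its kept probe with the highest mean log2 value over all arrays, which gave 12975 genes from 17745 kept probes, 3703 of them with more than 1 kept probe. FTH1 had no named probe and was not measured here.

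On the 6 WN arrays the deposited detection p-values did not follow the signals. On the other 12 arrays at least 99.99% of probes lay within 0.02 of a falling function of the signal of their own array (running median over 101 probes), whereas on the WN arrays 66.5% to 68.1% did, and 17387 probes were off on at least 1 of them. Detection p-values of these arrays were therefore rederived from their own signals by that function, a change made after seeing the data, and the deposited p-values were kept as an alternative. Genes whose probe was off on any WN array gave these calls: 183 of 3970 (4.61%) against 412 of 9005 (4.58%) with WN in IMR-32, and 77 (1.94%) against 161 (1.79%) in SK-N-SH.

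All 18 arrays were fitted together with limma (lmFit with 1 mean per group, 12 residual and 4.45 prior degrees of freedom, eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with 0.05 as the threshold. The comparisons were WA or WN against DMSO and WA against WN in each line, the difference between the lines in the WA and in the WN effect, and the untreated lines against each other. Intervals cover 95%. For each comparison the named genes were up to 10 higher and 10 lower with the largest change among those past the threshold, with both groups' arrays fully apart (not asked of the difference between lines) and detected on all 3 arrays of at least 1 group, up to 4 changed members of each described list with the largest change (or the 2 largest if none passed), and always HMOX1, KEAP1, NFE2L2, GPX4, SLC7A11, ACSL4, TFRC, FTH1, HSPA1A, DDIT3, MYCN and VIM. That rule, the comparisons, the gene lists and the first set of alternatives were fixed before the data were examined, and the text describes part of the genes so named.

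The 21 gene lists hold 541 symbols, of which 506 had a named probe and 450 were tested: NRF2 targets, heat shock response, unfolded protein response, integrated stress response, iron handling, ferroptosis regulators, glutathione and selenoproteins, cholesterol synthesis, p53 targets, DNA replication, mitosis, ribosome biogenesis, proteasome, autophagy, NF-kB targets, metallothioneins, immediate early genes, adrenergic neuroblast markers, mesenchymal markers, Schwann cell markers and immune cell markers. They were tested with camera at the preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, with adjustment over the lists of a comparison. Lists share members, for example 10 of the 34 NRF2 targets stand in another list. Of the Schwann cell markers 3 of 14 were measured.

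Replicate numbers were checked for pairing by correlating the deviations of arrays from their group means across genes. Within a line, WA or WN arrays and DMSO arrays of the same number gave r of 0.245, 0.191, 0.296 and 0.161, 0.170, 0.338 in IMR-32 and 0.318, 0.214, 0.308 and 0.458, 0.372, 0.663 in SK-N-SH, whereas across lines 2 of 27 pairs exceeded 0.1. The lowest r between WA and WN arrays of the same number was 0.0424, in SK-N-SH. The fit with the replicate number within each line as a block called 2550 genes with WA in IMR-32 and 4954 in SK-N-SH.

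Replicates of a group correlated at r between 0.956 and 0.993 over 13973 probes, and the SD of their differences lay between 0.234 and 0.610. The method was tested on simulated data with the spread of these arrays and 50 changed genes at each of 4 fold sizes for WA against DMSO in IMR-32: 24% were recovered at 1.5-fold, 84% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 10 false among 163 calls, 0 calls in either unchanged WN comparison (limma), and camera called the raised list and 0 others of 21. Whether this holds for correlated genes, paired replicates or lines of unequal spread was not shown. With 3 arrays per group precision is limited, and a change under 2-fold was often not detectable.

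Alternatives changed 1 choice at a time: no background correction, scaling to the median in place of quantile normalization, no detection filter or a filter on all arrays of a group, the mean of all probes of a gene, every probe tested, eBayes with trend and robust settings, array weights, the replicate number as a block, only the arrays compared, the deposited series matrix values, an estimated correlation in camera, stricter thresholds, and each array left out in turn. After the data had been seen these were added: scaling on the median of the probes detected on all arrays, the replicate number within each line as a block, WA comparisons without the 6 WN arrays, the deposited detection p-values on all arrays, the agreement of the other probes of a gene, each WA array held out, and the trend with level on median-scaled values. For the correlation of WA and WN effects unchanged groups were simulated from the replicate deviations of each line, with numbers kept together, and from 1 spread for both lines.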

Results

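Gene expression was measured in the neuroblastoma lines IMR-32 and SK-N-SH after 24 h with withaferin A (WA), withanone (WN) or the solvent DMSO, each compound at 1 µM, on 18 Illumina HumanHT-12 v4 arrays, with 3 biological replicates per group per the labels. IMR-32 is a line known to carry amplified MYCN, whereas SK-N-SH is known to lack that amplification. Withaferin A and withanone are both withanolides, steroidal lactones of the plant Withania somnifera, and differ in the positions of an epoxide and of hydroxyl groups. The series concerns the induction of ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation, in high-risk neuroblastoma. Of 12975 genes tested, values are given as log2 differences between group means ± the standard error of the fit, with 3 arrays per group and adjusted p from limma, and each is relative to the median of all genes, which quantile normalization holds near 0. For every gene named as changed between 2 groups the 3 arrays of one group all lay beyond the 3 of the other, except TFRC between WA and WN in SK-N-SH (2 of 3).

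The 6 WN arrays were dimmer than the other 12. Their highest signal lay between 19100.5 and 21479.9 against 29825.6 to 37328.5 on the DMSO and WA arrays, and the median signal of the probes detected on all arrays lay between 279.7 and 436 against 435 to 567. Between 17102 and 20013 probes were detected on a WN array and between 17773 and 20781 on another array. By highest signal no WN array lay among the others, so that this brightness and the WN groups cannot be told apart, whereas by the median signal and the number of detected probes the sets overlapped. The first principal component of the gene values, with 70.6% of the variance, separated the lines.

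**Figure D1:**
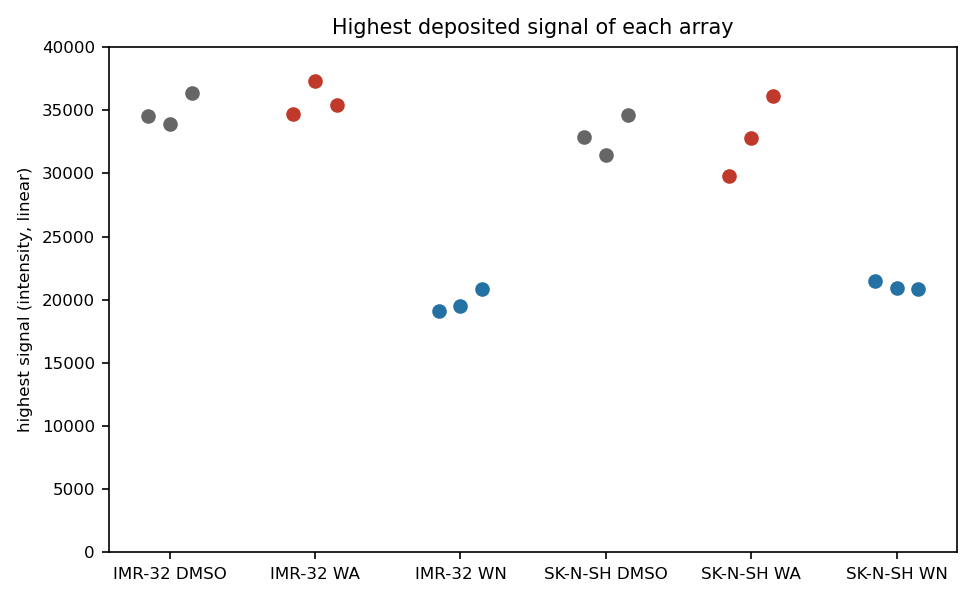
Highest deposited signal of each array (intensity on a linear axis that starts at 0) for the 6 groups, 1 point per array. The 6 WN arrays sit between 19100.5 and 21479.9, and the 12 others between 29825.6 and 37328.5.

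The largest rises with WA in IMR-32 cells were those of HMOX1 and of aldo-keto reductase genes. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 67.6-fold (log2 6.08 ± 0.32, n = 3 per group, adjusted p = 5.87e-09), the largest change of the comparison. GDF15, a cytokine induced by cell stress, rose by 4.18 ± 0.54, and the quinone reductase NQO1 rose by 3.26 ± 0.24, although its dimmer probe gave 1.13. The aldo-keto reductases AKR1C3 (5.55 ± 0.38), AKR1C4 (4.40 ± 0.28) and AKR1C2 (4.38 ± 0.31) rose as well, but these paralogs are nearly identical and their probes may not tell them apart. Among the genes that fell most were the chemokine receptor CXCR4 (−3.46 ± 0.53), the serotonin receptor subunit HTR3A (−3.11 ± 0.16), DBH, the enzyme of noradrenaline synthesis (−2.80 ± 0.61), the transcription factor CEBPD (−2.77 ± 0.61) and TXNIP, an inhibitor of thioredoxin (−2.38 ± 0.22).

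In all, 1883 genes passed an adjusted p of 0.05 in IMR-32, 1043 higher and 840 lower with WA, and 492 of them changed at least 2-fold. HEY1, a Notch target, rose by 3.04 ± 0.27 and the neuropeptide precursor VGF by 2.88 ± 0.27. ANXA1, which encodes annexin A1 and was undetected on all DMSO arrays, was at least 7.48-fold higher (5.59 to 12.6 with single arrays left out) (adjusted p = 3.12e-05). Such a bound sets the mean of the bright group over its 3 arrays against the dim group's mean of, per array, the higher of the detection floor and the gene's own value. For 40.4% of genes WA and DMSO arrays lay fully apart, against 10% by chance. The count was 1250 or 1209 without DMSO replicate 1 or 3, and 1123 or 1150 without WA replicate 1 or 2.

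Of the genes followed in every comparison, SLC7A11, the cystine transporter subunit of system xc-, was undetected on the DMSO arrays of IMR-32 and at least 2.26-fold higher with WA (adjusted p = 0.00191). DDIT3, which encodes the stress transcription factor CHOP, rose by 2.38 ± 0.30 (adjusted p = 8.02e-05). KEAP1, the adaptor that targets NRF2 for degradation, rose by 0.53 ± 0.13 (adjusted p = 0.0124), a call lost without DMSO replicate 3 (0.49) and without WA replicate 1 (0.47). GPX4, the selenoenzyme that reduces lipid hydroperoxides, gave 0.02 ± 0.14 with a 95% interval of −0.27 to 0.31, and ACSL4, which supplies polyunsaturated acyl chains to phospholipids, gave 0.02 ± 0.22 (−0.46 to 0.49). The transferrin receptor TFRC gave −0.01 ± 0.15, NFE2L2, which encodes NRF2, 0.23 ± 0.21 and MYCN −0.29 ± 0.36, none past the threshold. VIM, which encodes vimentin, gave 0.50 ± 0.24 (adjusted p = 0.188), and the same difference passed with the replicate number within the line as a block. HSPA1A was undetected in both groups.

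Grouped by gene lists, the NRF2 targets rose together in IMR-32: 19 of 27 measured members rose and 0 fell (20 and 0 over the list alone, median 0.96, camera adjusted p = 1.86e-18, 0.0132 with an estimated correlation). This call held. GCLM, the modifier subunit of glutamate-cysteine ligase, rose by 1.60 ± 0.25. Of the heat shock genes 10 of 26 rose (same over the list alone, median 0.39, camera adjusted p = 0.000103, 0.158 with an estimated correlation). ZFAND2A stood at 1.42 ± 0.30, DNAJB4 at 1.40 ± 0.30 and HSPA1B at 1.38 ± 0.32. Of the integrated stress response genes 12 of 27 rose (13 and 0 over the list alone, median 0.34, camera adjusted p = 1.09e-05, 0.239 with an estimated correlation). Among them were PPP1R15A (1.92 ± 0.33) and SLC3A2 (1.71 ± 0.24). The unfolded protein response list had 1 member higher and 3 lower of 19 (same over the list alone, median 0.08, camera adjusted p = 0.971), and its mean was 0.02 with a test in the downward direction. Of the immediate early genes 8 of 21 rose (11 and 0 over the list alone, median 0.62, camera adjusted p = 0.000189, 0.138 with an estimated correlation). FOS stood at 2.76 ± 0.44 and EGR1 at 2.73 ± 0.56. The median of that list was 0.47 with undetected genes at their bounds.

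Among the redox and iron lists of IMR-32, 7 of 20 ferroptosis regulators rose (7 and 1 over the list alone, median 0.16, camera adjusted p = 0.00269, 0.104 with an estimated correlation). Among them was AIFM2, which encodes a reductase of ubiquinone (1.56 ± 0.22). Of the glutathione and selenoprotein genes 8 of 34 rose and 2 fell (9 and 2 over the list alone, median 0.23, camera adjusted p = 0.000771, 0.104 with an estimated correlation). GPX3 stood at 2.60 ± 0.14 and TXNRD1 at 1.13 ± 0.21. Of the iron genes 3 of 20 rose and 1 fell (same over the list alone, median 0.07, camera adjusted p = 0.145). Among them were HMOX1 and the biliverdin reductase BLVRB (2.47 ± 0.24). The p53 targets had 6 of 21 higher (9 and 0 over the list alone, median 0.40, camera adjusted p = 0.000153, 0.104 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at 1.07 ± 0.22. Of the autophagy genes 5 of 25 rose (same over the list alone, median 0.35, camera adjusted p = 0.000153, 0.104 with an estimated correlation). The receptor SQSTM1 stood at 1.94 ± 0.23 and MAP1LC3B at 0.75 ± 0.12. Of the proteasome genes 12 of 27 rose (14 and 0 over the list alone, median 0.38, camera adjusted p = 6.35e-08, 0.104 with an estimated correlation). PSMD3 stood at 0.69 ± 0.13 and PSMC2 at 0.60 ± 0.11.

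Genes of DNA replication and of ribosome biogenesis fell in IMR-32. Of the replication genes 14 of 31 fell and 0 rose (0 and 21 over the list alone, median −0.63, camera adjusted p = 1.67e-10, 0.209 with an estimated correlation). Among them was CDC45 (−1.07 ± 0.27, not past the threshold without WA replicate 2, −0.99). Of the ribosome biogenesis genes 12 of 28 fell (1 and 14 over the list alone, median −0.42, camera adjusted p = 9.95e-08, 0.0132 with an estimated correlation), a call that held, with NOP14 at −0.75 ± 0.13. The mitosis list had 0 genes higher and 0 lower of 35 in limma (1 higher and 1 lower at an unadjusted p under 0.05, same over the list alone, median 0.16, camera adjusted p = 0.638). The fit gives each gene 1 spread over both lines. Where SK-N-SH arrays scatter more, errors come out too wide in IMR-32 and too narrow in SK-N-SH. CCNB2 had SDs of 0.10 (WN) and 0.06 (DMSO) in IMR-32 but an SE of 0.44. These counts thus do not show unchanged mitosis genes. The adrenergic neuroblast markers had 2 higher and 3 lower of 26 (same over the list alone, median −0.09, camera adjusted p = 0.571). SCG2 stood at 2.15 ± 0.25, INSM1 at −2.19 ± 0.29 and ISL1 at −1.72 ± 0.20. The mesenchymal markers had 4 higher and 2 lower of 30 (5 and 2 over the list alone, median 0.19, camera adjusted p = 0.0810, and 0.0295 with the replicate number within the line as a block). SNAI2 stood at 2.02 ± 0.36 and LOX, undetected with WA, at least 3.00-fold lower.

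The remaining lists of IMR-32 held few changes. The cholesterol synthesis genes had 2 higher and 1 lower of 18 (same over the list alone, median 0.08, camera adjusted p = 0.571), and the NF-kB targets 1 higher and 0 lower of 14 (same over the list alone, median 0.14, camera adjusted p = 0.571). Of 6 measured genes of the metallothionein list 0 rose and 0 fell in limma (1 higher and 1 lower at an unadjusted p under 0.05, same over the list alone, median 0.02, camera adjusted p = 0.978, mean −0.02 and a downward test). The Schwann cell list had 1 of 3 measured genes lower, NGFR (−1.21 ± 0.23, same over the list alone, median −0.09, camera adjusted p = 0.236, median −1.21 with bounds). The immune cell list had 1 higher and 1 lower of 9 (same over the list alone, median 0.04, camera adjusted p = 0.775, mean −0.01 and a downward test). The fry test asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes, and for the iron list it gave an adjusted p of 0.000241 in IMR-32 and 1.63e-05 in SK-N-SH.

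In SK-N-SH cells WA raised HMOX1 183-fold (log2 7.51 ± 0.32, n = 3 per group, adjusted p = 4.95e-10), again the largest rise. GDF15 rose by 4.35 ± 0.54, the immediate early transcription factor EGR1 by 3.66 ± 0.56, the noncoding RNA RN7SK by 3.60 ± 0.33, the polyamine acetyltransferase SAT1 by 3.56 ± 0.37, DDIT3 by 3.51 ± 0.30, the inducible chaperone HSPA6 by 3.40 ± 0.63 and TRIB3, a target of the transcription factor ATF4, by 3.38 ± 0.32. TXNIP fell most (−4.47 ± 0.22), and among others that fell were the phosphatase PPEF1 (−4.17 ± 0.45), the neuroendocrine transcription factor INSM2 (−4.16 ± 0.57), TMEM100 (−3.25 ± 0.38) and CHGA, the secretory granule protein chromogranin A (−2.88 ± 0.50). MYCN was undetected with WA and at least 6.51-fold lower than with DMSO (adjusted p = 1.16e-05), while its dimmer probe gave −0.90.

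With WA 4134 genes changed in SK-N-SH, 2130 higher and 2004 lower, and 1251 of them at least 2-fold. Among the genes followed throughout, SLC7A11 rose by 2.83 ± 0.32, HSPA1A by 3.11 ± 0.32, NFE2L2 by 1.22 ± 0.21 and KEAP1 by 0.73 ± 0.13. GPX4 gave −0.10 ± 0.14 (adjusted p = 0.625, 95% interval −0.39 to 0.19), ACSL4 0.30 ± 0.22 (−0.17 to 0.77) and VIM 0.06 ± 0.24 (−0.44 to 0.57), none past the threshold. TFRC gave 0.38 ± 0.15 (adjusted p = 0.0700), which passed with the replicate number within the line as a block and, at 0.57, without WA replicate 2. WA and DMSO arrays lay fully apart for 35.8% of genes, against 10% by chance.

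**Figure D2:**
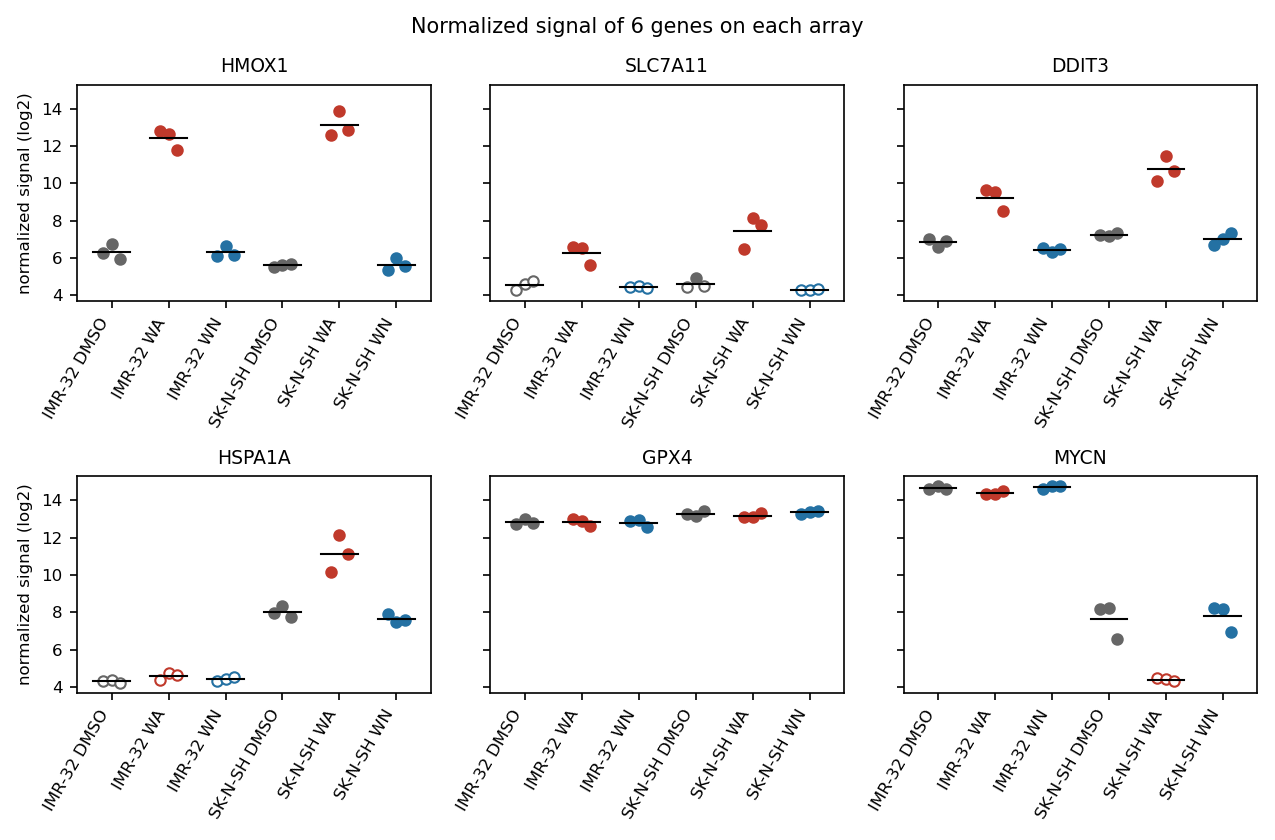
Normalized log2 signal of HMOX1, SLC7A11, DDIT3, HSPA1A, GPX4 and MYCN on each array of the 6 groups, with filled points for arrays on which the gene was detected, open points for the others and a bar at the group mean. HMOX1 sat 6.08 log2 units above DMSO with WA in IMR-32 and 7.51 in SK-N-SH, while GPX4 differed from DMSO by 0.02 and −0.10.

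Each WA array was held out in turn and its deviation from DMSO set against the mean effect of the other 2. The slope was 0.490 for SK-N-SH replicate 1, 1.13 and 1.10 for replicates 2 and 3, and 1.02, 1.03 and 0.767 in IMR-32, so medians are given per array for several lists of SK-N-SH. NRF2 targets rose in 24 of 27 cases (25 and 0 over the list alone, median 1.35, camera adjusted p = 1.22e-18, 0.0271 with an estimated correlation), a call that held. Their median was 1.39, 1.36 and 1.44 on replicates 1 to 3. GCLM rose by 3.10 ± 0.25 and SRXN1, which encodes sulfiredoxin, by 3.05 ± 0.21. Integrated stress response genes rose in 24 of 27 cases (same over the list alone, median 1.79, camera adjusted p = 1.22e-18, 0.0747 with an estimated correlation), with medians of 1.41, 2.17 and 1.81 on replicates 1 to 3. The amino acid transporter chain SLC3A2 rose by 3.28 ± 0.24, and CHAC1, a glutathione-degrading enzyme undetected with DMSO, was at least 7.37-fold higher. Heat shock genes rose in 17 of 26 cases (same over the list alone, median 0.75, camera adjusted p = 1.10e-08, 0.0747 with an estimated correlation), with medians of 0.61, 1.04 and 0.71 on replicates 1 to 3 and with HSPA1B at 2.26 ± 0.32.

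Genes of cell division fell in SK-N-SH. Of the replication genes 29 of 31 fell (same over the list alone, median −1.44, camera adjusted p = 2.57e-18, 0.106 with an estimated correlation), led by RRM2, a subunit of ribonucleotide reductase (−2.29 ± 0.32), and UHRF1 (−2.12 ± 0.26). The median of the replication list was −0.80, −1.58 and −1.84 on replicates 1 to 3. Of the mitosis genes 33 of 35 fell (0 and 34 over the list alone, median −1.53, camera adjusted p = 2.13e-13, 0.198 with an estimated correlation). Topoisomerase TOP2A stood at −2.36 ± 0.38, the kinase AURKB at −2.25 ± 0.47 and MKI67, the Ki-67 antigen, at −2.15 ± 0.48. The median of the mitosis list was −0.37, −1.50 and −2.71 on replicates 1 to 3. The adrenergic neuroblast markers fell in 12 of 26 cases (same over the list alone, median −0.93, camera adjusted p = 2.04e-05, 0.198 with an estimated correlation), among them the nicotinic receptor subunit CHRNA3 (−2.28 ± 0.33). Their median was −0.32, −0.91 and −1.47 on replicates 1 to 3. The mesenchymal markers had 2 higher and 5 lower of 30 (same over the list alone, median −0.16, camera adjusted p = 0.373). Thrombospondin THBS1 stood at −2.02 ± 0.31 and LOX at 1.27 ± 0.29. Ribosome biogenesis had 1 higher and 9 lower of 28 (same over the list alone, median −0.23, camera adjusted p = 0.0170, 0.146 with an estimated correlation). The nucleolar protein FBL stood at −0.94 ± 0.16.

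Proteasome genes of SK-N-SH rose in 14 of 27 cases (15 and 0 over the list alone, median 0.37, camera adjusted p = 2.10e-06, 0.146 with an estimated correlation). PSMD8 stood at 1.07 ± 0.15. Autophagy genes had 13 higher and 1 lower of 25 (14 and 1 over the list alone, median 0.62, camera adjusted p = 2.26e-05, 0.0808 with an estimated correlation). SQSTM1 stood at 2.29 ± 0.23 and GABARAPL1 at 2.01 ± 0.25. The p53 targets had 12 higher and 1 lower of 21 (13 and 1 over the list alone, median 0.62, camera adjusted p = 0.000106, 0.106 with an estimated correlation). PHLDA3 stood at 1.43 ± 0.21 and CDKN1A at 1.40 ± 0.22. The immediate early genes had 12 higher and 1 lower of 21 (same over the list alone, median 0.86, camera adjusted p = 0.000552, 0.146 with an estimated correlation). FOS stood at 3.02 ± 0.44 and DUSP5 at 2.96 ± 0.32. Their list median was 0.60, 1.18 and 1.08 on replicates 1 to 3. The unfolded protein response had 6 of 19 higher (same over the list alone, median 0.28, camera adjusted p = 0.0295, 0.266 with an estimated correlation). DNAJC3 stood at 1.62 ± 0.22 and XBP1 at 1.22 ± 0.21.

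Of the ferroptosis regulators of SK-N-SH 8 of 20 rose and 2 fell (10 and 2 over the list alone, median 0.33, camera adjusted p = 0.00101, 0.0747 with an estimated correlation), among the risers SAT1, SLC3A2 and SLC7A11. Glutathione and selenoprotein genes had 11 higher and 3 lower of 34 (11 and 4 over the list alone, median 0.17, camera adjusted p = 0.0225, 0.198 with an estimated correlation). TXNRD1 stood at 2.69 ± 0.21. Iron genes had 4 of 20 higher (same over the list alone, median 0.24, camera adjusted p = 0.0614), with a median of 0.31 past the threshold without DMSO replicate 3, and with BLVRB at 1.75 ± 0.24. Cholesterol synthesis genes had 2 higher and 5 lower of 18 (2 and 6 over the list alone, median −0.10, camera adjusted p = 0.227). EBP stood at −0.93 ± 0.20. The NF-kB targets had 1 of 14 higher (0 and 0 over the list alone, median 0.06, camera adjusted p = 0.759). The metallothionein list had 1 higher, the zinc exporter SLC30A1 (1.06 ± 0.22), and 1 lower, MT1F (−1.96 ± 0.32), of 6 (same over the list alone, median −0.02, camera adjusted p = 0.907). Markers of other cell types had 2 of 3 higher for Schwann cells (same over the list alone, median 0.74, camera adjusted p = 0.227). Immune cell markers had 4 higher and 1 lower of 9 (same over the list alone, median 0.23, camera adjusted p = 0.109, median 0.43 with bounds). Among them was CD68, a lysosomal protein of macrophages (1.13 ± 0.20).

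**Figure D3:**
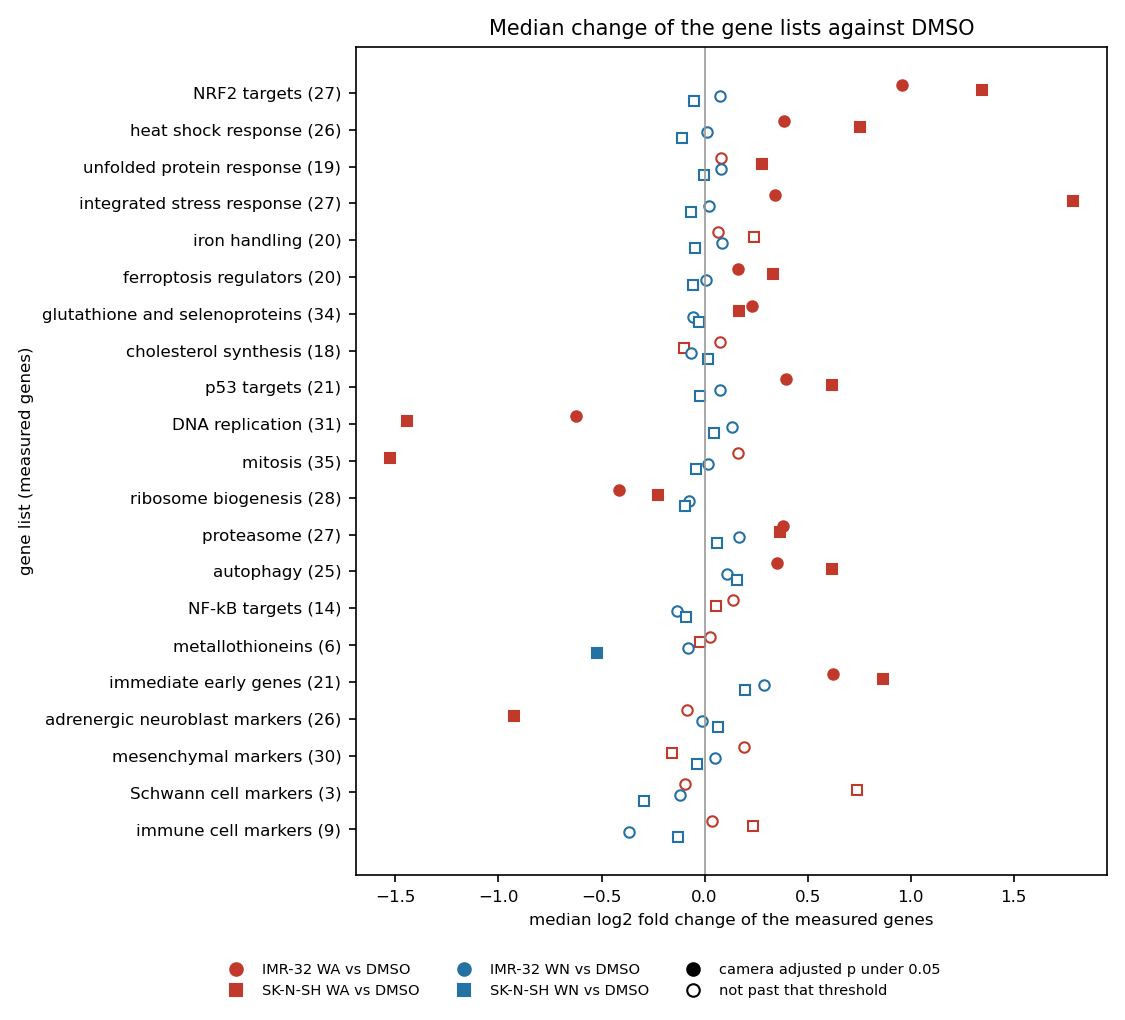
Median log2 fold change against DMSO of the measured genes of the 21 lists, for WA (red) and WN (blue) in IMR-32 (circles) and SK-N-SH (squares), filled where camera gave an adjusted p under 0.05. The NRF2 targets sit at 0.96 and 1.35 with WA, and at 0.08 and −0.05 with WN.

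The lines shared much of the WA effect. Of the called genes 596 rose in both lines, against 171 for independent lists, 382 fell in both, against 129.7, and 44 moved in opposite directions, against 299. Pearson's r of the WA effects across genes, which are not independent replicates, was 0.475 and Spearman's rho 0.473. HMOX1, GDF15 and DDIT3 rose and TXNIP fell in both lines. The overlap of 978 genes fell to 644 without IMR-32 DMSO replicate 3, and 589 or 609 without WA replicate 1 or 2.

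The test of the difference between the lines, the WA effect in SK-N-SH minus that in IMR-32, called 864 genes, 429 higher and 435 lower in SK-N-SH. Among the largest positive differences were those of CEBPD (3.95 ± 0.87, adjusted p = 0.0132), LOX (3.27 ± 0.41), the carbonic anhydrase CA12 (2.98 ± 0.54), HTR3A (2.96 ± 0.23), VEGFD (2.91 ± 0.21) and HSPA1A (2.82 ± 0.45, adjusted p = 0.00196). For LOX, HTR3A, VEGFD and HSPA1A at least 1 group was undetected, so the size depends on the floor. The largest negative differences were those of AKR1C3 (−3.99 ± 0.53), TMEM100 (−3.92 ± 0.54), PPEF1 (−3.48 ± 0.64), AKR1C2 (−3.45 ± 0.44) and FAM167A (−3.35 ± 0.69), and TMEM100 was undetected in IMR-32 with DMSO. MYCN, undetected in SK-N-SH with WA and near the top of the scale in IMR-32, differed by −2.97 ± 0.51 (adjusted p = 0.00307). Its dimmer probe gave −0.33 in IMR-32 and −0.90 in SK-N-SH, so that size is not exact and depends on the probe. HMOX1 (1.43 ± 0.45, adjusted p = 0.0649), SLC7A11 (1.12 ± 0.45, 0.148), DDIT3 (1.13 ± 0.43, 0.128) and GPX4 (−0.12 ± 0.19, 0.786) did not pass this test.

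By lists, the integrated stress response rose further in SK-N-SH, with 12 of 27 genes higher (21 and 1 over the list alone, median 1.07, camera adjusted p = 1.93e-14, 0.344 with an estimated correlation). Among them were CEBPB (2.53 ± 0.40), the amino acid transporter SLC7A5 (2.48 ± 0.28) and SLC3A2 (1.57 ± 0.34). The NRF2 targets had 6 higher and 2 lower of 27 (11 and 3 over the list alone, median 0.35, camera adjusted p = 0.0123, 0.368 with an estimated correlation). TXNRD1 stood at 1.56 ± 0.29. The heat shock list had 1 gene higher of 26 (same over the list alone, median 0.34, camera adjusted p = 0.00141, 0.368 with an estimated correlation). The unfolded protein response had 1 of 19 higher (0 and 0 over the list alone, median 0.27, camera adjusted p = 0.0123, 0.368 with an estimated correlation). The Schwann cell markers had 1 of 3 higher (2 and 0 over the list alone, median 1.00, camera adjusted p = 0.0179, 0.368 with an estimated correlation). Mitosis genes had 6 of 35 lower (0 and 35 over the list alone, median −1.65, camera adjusted p = 2.08e-16, 0.368 with an estimated correlation). Replication genes had 4 of 31 lower (0 and 12 over the list alone, median −0.80, camera adjusted p = 1.22e-07, 0.368 with an estimated correlation). The adrenergic markers had 2 higher and 7 lower of 26 (2 and 13 over the list alone, median −0.86, camera adjusted p = 0.000458, 0.368 with an estimated correlation). The neurofilament gene NEFM stood at −3.32 ± 0.67. The mesenchymal markers had 1 higher and 5 lower of 30 (same over the list alone, median −0.45, camera adjusted p = 0.0123, 0.518 with an estimated correlation). None of these list calls held with an estimated correlation. The ferroptosis regulators, at a median of 0.24 (camera adjusted p = 0.0530), passed without IMR-32 WA replicate 1 (0.23), SK-N-SH DMSO replicate 3 (0.33), SK-N-SH WA replicate 1 (0.32) or SK-N-SH WA replicate 2 (0.24), and no other list passed with all arrays.

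The count of genes whose WA effect differed between the lines moved with single arrays. It was 2236 without SK-N-SH WA replicate 1, and it was lower without IMR-32 DMSO replicates 1 (526), 2 (548) and 3 (555), IMR-32 WA replicates 1 (519) and 2 (538), SK-N-SH DMSO replicate 1 (553) and SK-N-SH WA replicate 2 (534). With the replicate number within each line as a block it was 1751, and without the 6 WN arrays 551.

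With WN 595 genes passed in IMR-32, 311 higher and 284 lower, and 48 of them by at least 2-fold. That WN changed fewer genes than WA there depends on the scaling, since median scaling gave 3090 with WN and 1230 with WA. The neuronal transcription factor NEUROD2 rose by 1.45 ± 0.23 (n = 3 per group, adjusted p = 0.00528), the ubiquitin ligase RNF13 by 1.12 ± 0.19 and the chloride channel gene TTYH3 by 1.10 ± 0.19. The spliceosomal RNA RNU4-2 fell most (−1.78 ± 0.39). The histone genes H4C12 (−1.35 ± 0.22) and H4C11 (−1.26 ± 0.19), the cap methyltransferase gene TGS1 (−1.29 ± 0.21), MTLN, which encodes a mitochondrial micropeptide (−1.26 ± 0.18), MYCNOS, the antisense transcript of MYCN (−1.24 ± 0.17), and the small nucleolar RNA SNORD104 (−1.23 ± 0.17) fell, and SNORD8, undetected with WN, was at least 1.48-fold lower. Several of these RNAs lack a poly(A) tail, and whether RNA preparation or labelling differed was not tested. The dimmer probes of RNF13 and TGS1, both near the floor, gave −0.265 and −0.091. Of the heat shock list the constitutive chaperone HSPA8 rose by 0.67 ± 0.12, and of the cholesterol list SC5D by 1.01 ± 0.16. None of the genes followed throughout passed. HMOX1 gave −0.04 ± 0.32 with a 95% interval of −0.71 to 0.63, GPX4 −0.05 ± 0.14 (−0.34 to 0.24). ACSL4 gave −0.79 ± 0.22 (adjusted p = 0.0527), and it passed with the replicate number within the line as a block and, at −0.92, without WN replicate 3.

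These IMR-32 WN arrays had a mean highest signal of 19808 ± 902 (SD, n = 3) against 34946 ± 1292 with DMSO. Scaling each array to its median in place of quantile normalization moved the median of all genes by −0.37 and gave 27 higher and 3063 lower genes, while scaling on the median of probes detected on all arrays moved it by 0.13 and gave 590 and 280, so the directions above are relative to the median gene. The WN arrays lay fully apart from DMSO for 31.5% of genes, against 10% by chance. The count of 595 was 987 with the replicate number within the line as a block, and without single arrays it was 125 (DMSO replicate 1), 220 (DMSO replicate 2), 161 (DMSO replicate 3), 223 (WN replicate 1) and 165 (WN replicate 2).

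In SK-N-SH 238 genes passed with WN, 120 higher and 118 lower. P2RY11, which encodes a nucleotide receptor, fell by 1.09 ± 0.12 (n = 3 per group, adjusted p = 0.00154), SNORD104 gave −1.07 ± 0.17 and the ribosomal protein gene RPL21 −1.04 ± 0.17, while SPIN1, which encodes a reader of histone methylation, gave 1.69 ± 0.37 and the zinc finger gene ZNF394 1.37 ± 0.22 (dimmer probe 0.202). Without WN replicate 1 the count was 1, and of the genes named here the call of P2RY11 alone was kept, with a log2 fold change between −1.15 and −0.98 over the arrays left out in turn. HMOX1 gave 0.05 ± 0.32 (−0.63 to 0.72), GPX4 0.09 ± 0.14 (−0.20 to 0.39) and ACSL4 −0.66 ± 0.22 (adjusted p = 0.146, past the threshold with the replicate number within the line as a block). Of 6 genes of the metallothionein list 0 rose and 0 fell in limma (0 higher and 4 lower at an unadjusted p under 0.05, 0 and 2 over the list alone, median −0.52, camera adjusted p = 0.0458, 0.987 with an estimated correlation). MT1E stood at −0.68 ± 0.21 and MT1G at −0.57 ± 0.16, not past the threshold. No other list passed in either line with WN.

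The SK-N-SH WN arrays, too, were dim, with a mean highest signal of 21084 ± 349.8 (SD, n = 3) against 32983 ± 1581 with DMSO. Median scaling moved the median of all genes by −0.25 and gave 24 higher and 534 lower genes, and scaling on the detected probes gave 106 and 64. With only the 6 arrays compared in the limma fit 0 genes passed, although 1948 had an unadjusted p under 0.05. The count was 318 with the replicate number as a block, 495 with the number within each line, and without single arrays 30 (DMSO replicate 1), 128 (DMSO replicate 2), 55 (DMSO replicate 3), 26 (WN replicate 2) and 152 (WN replicate 3). WN arrays lay fully apart from DMSO for 21.8% of genes, against 10% by chance.

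Between the lines 44 genes rose with WN in both, against 2.88 for independent lists, 60 fell in both, against 2.58, and 0 went in opposite directions, against 5.45, all on arrays that were dim in both lines. Pearson's r of the WN effects across genes, which are not independent replicates, was 0.590 and Spearman's rho 0.585. For the difference of the WN effects between the lines limma called 0 genes, with 478 at an unadjusted p under 0.05 and 0 with only the 12 WN and DMSO arrays (659 unadjusted), and 2 without IMR-32 WN replicate 3. By lists, the immune cell markers had 0 higher and 0 lower of 9 genes (3 higher and 0 lower at an unadjusted p under 0.05, 3 and 0 over the list alone, median 0.35, camera adjusted p = 0.000654, 0.0206 with an estimated correlation), a call that held but rests in part on dim genes, since 3 of 9 were detected on all DMSO arrays, and on 1 probe each of CD68 and HLA-DRA. The metallothionein list had 0 and 0 (0 higher and 3 lower at an unadjusted p under 0.05, 0 and 2 over the list alone, median −0.45, camera adjusted p = 0.0254, 0.940 with an estimated correlation). Median scaling moved the median of all genes by 0.13 in this difference.

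At the same dose and time WA and WN arrays of IMR-32 differed in 3081 genes, 1631 higher and 1450 lower with WA. All WN arrays were dim, so in both lines part of these differences may come from their handling. HMOX1 was 69.3-fold higher with WA than with WN (log2 6.11 ± 0.32, n = 3 per group, adjusted p = 3.27e-09), the noncoding RNAs RNA5S9 and RN7SK higher by 3.60 ± 0.30 and 3.28 ± 0.33 (against DMSO 2.77 and 2.46), BLVRB by 3.06 ± 0.24 and DDIT3 by 2.77 ± 0.30. ACSL4 was higher by 0.81 ± 0.22 (adjusted p = 0.0150), from 0.02 with WA and −0.79 with WN against DMSO (dimmer probe 0.038 and −0.135). SLC7A11 was undetected with WN and at least 2.13-fold higher with WA. CXCR4 (−3.64 ± 0.53), the angiogenic factor gene VEGFD (−2.91 ± 0.15) and the chemokine gene CXCL12 (−2.47 ± 0.21) were lower with WA. GPX4 differed by 0.07 ± 0.14 (interval −0.22 to 0.36), KEAP1 by 0.29 ± 0.13 (0.01 to 0.57) and NFE2L2 by −0.03 ± 0.21 (−0.47 to 0.41). TFRC gave −0.26 ± 0.15 (−0.58 to 0.06), MYCN −0.32 ± 0.36 (−1.08 to 0.43) and VIM 0.18 ± 0.24 (−0.32 to 0.69), none past the threshold.

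Of the NRF2 targets 21 of 27 were higher and 1 lower with WA than with WN in IMR-32 (21 and 2 over the list alone, median 0.93, camera adjusted p = 6.58e-14, 0.0532 with an estimated correlation), with GPX3, which the glutathione list holds, at 2.79 ± 0.14 and the autophagy receptor SQSTM1 at 2.03 ± 0.23. Replication genes were lower in 23 of 31 cases (0 and 26 over the list alone, median −0.76, camera adjusted p = 1.42e-10, 0.405 with an estimated correlation). Ribosome biogenesis genes were lower in 13 of 28 (1 and 14 over the list alone, median −0.40, camera adjusted p = 9.79e-05, 0.0532 with an estimated correlation), and with median scaling a median 0.24 below that of all genes. Heat shock response had 10 of 26 genes higher and 2 lower (same over the list alone, median 0.28, camera adjusted p = 0.00359, 0.425 with an estimated correlation). Integrated stress response had 11 of 27 genes higher and 0 lower (same over the list alone, median 0.34, camera adjusted p = 0.000826, 0.446 with an estimated correlation). Ferroptosis regulators had 8 of 20 genes higher and 1 lower (same over the list alone, median 0.20, camera adjusted p = 0.0177, 0.235 with an estimated correlation). Glutathione and selenoproteins had 11 of 34 genes higher and 2 lower (14 and 3 over the list alone, median 0.30, camera adjusted p = 0.000826, 0.197 with an estimated correlation). P53 targets had 7 of 21 genes higher and 0 lower (same over the list alone, median 0.32, camera adjusted p = 0.0104, 0.405 with an estimated correlation). Proteasome had 7 of 27 genes higher and 0 lower (same over the list alone, median 0.23, camera adjusted p = 0.00359, 0.446 with an estimated correlation). No list call of this comparison held with an estimated correlation. Median scaling moved the median of all genes by 0.38 and gave 4493 higher and 277 lower genes, and scaling on the detected probes moved it by −0.16 and gave 1220 and 2262. Without WA replicate 2 the count was 2006, and 43.4% of all genes lay fully apart, against 10% by chance.

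In SK-N-SH WA and WN differed in 4969 genes, 2679 higher and 2290 lower with WA. HMOX1 was 177-fold higher (log2 7.47 ± 0.32, n = 3 per group, adjusted p = 5.45e-10), DDIT3 higher by 3.72 ± 0.30, the sphingosine kinase SPHK1 by 3.50 ± 0.39, SAT1 by 3.49 ± 0.37, HSPA1A by 3.49 ± 0.32 and NFE2L2 by 1.19 ± 0.21. KEAP1 was higher by 0.82 ± 0.13, ACSL4 by 0.95 ± 0.22 (adjusted p = 0.00312) and TFRC by 0.42 ± 0.15 (adjusted p = 0.0398). SLC7A11, undetected with WN, was at least 5.68-fold higher with WA. MYCN, undetected with WA, was at least 7.11-fold lower, but its dimmer probe gave −0.90 with WA and 0.30 with WN against DMSO. TXNIP (−4.11 ± 0.22), the neuronal membrane protein gene LRRN3 (−3.14 ± 0.41) and the adenylate cyclase gene ADCY1 (−3.12 ± 0.50) were lower. GPX4 differed by −0.19 ± 0.14 (−0.49 to 0.10) and VIM by −0.10 ± 0.24 (−0.61 to 0.40), neither past the threshold.

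The NRF2 targets of SK-N-SH were higher with WA than with WN in 25 of 27 cases (same over the list alone, median 1.39, camera adjusted p = 3.30e-16, 0.0476 with an estimated correlation), which held. Integrated stress response genes were higher in 25 of 27 (26 and 0 over the list alone, median 1.69, camera adjusted p = 2.21e-16, 0.0905 with an estimated correlation). Among them was SLC3A2 (3.35 ± 0.24). Mitosis genes were lower in 30 of 35 (0 and 33 over the list alone, median −1.42, camera adjusted p = 9.46e-12, 0.235 with an estimated correlation). Ribosome biogenesis had 4 higher and 8 lower of 28 (same over the list alone, median −0.28, camera adjusted p = 0.0499, 0.225 with an estimated correlation, and 0.0690 with the replicate number within the line as a block), and with median scaling a median 0.15 below that of all genes. Heat shock response had 20 of 26 genes higher and 0 lower (21 and 0 over the list alone, median 0.80, camera adjusted p = 4.32e-08, 0.0916 with an estimated correlation). Unfolded protein response had 10 of 19 genes higher and 1 lower (same over the list alone, median 0.40, camera adjusted p = 0.01002, 0.225 with an estimated correlation). Ferroptosis regulators had 10 of 20 genes higher and 0 lower (same over the list alone, median 0.40, camera adjusted p = 0.00119, 0.0905 with an estimated correlation). Glutathione and selenoproteins had 15 of 34 genes higher and 5 lower (16 and 5 over the list alone, median 0.29, camera adjusted p = 0.0209, 0.225 with an estimated correlation). P53 targets had 11 of 21 genes higher and 1 lower (13 and 2 over the list alone, median 0.57, camera adjusted p = 0.000499, 0.170 with an estimated correlation). DNA replication had 0 of 31 genes higher and 28 lower (0 and 29 over the list alone, median −1.50, camera adjusted p = 6.10e-17, 0.166 with an estimated correlation). Proteasome had 11 of 27 genes higher and 0 lower (same over the list alone, median 0.29, camera adjusted p = 0.000400, 0.225 with an estimated correlation). Autophagy had 12 of 25 genes higher and 1 lower (same over the list alone, median 0.46, camera adjusted p = 0.00188, 0.1999 with an estimated correlation). Immediate early genes had 8 of 21 genes higher and 3 lower (11 and 3 over the list alone, median 0.54, camera adjusted p = 0.0240, 0.274 with an estimated correlation). Adrenergic neuroblast markers had 0 of 26 genes higher and 13 lower (same over the list alone, median −1.11, camera adjusted p = 1.03e-05, 0.225 with an estimated correlation). Median scaling moved the median of all genes by 0.20 and gave 3418 higher and 1163 lower genes, and scaling on the detected probes moved it by −0.04 and gave 2328 and 2460. Of all genes 42.9% lay fully apart, against 10% by chance.

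WA and WN were set against the same DMSO arrays. In IMR-32 60 genes rose with both compounds (independent lists 25), 68 fell with both (18.4) and 24 went in opposite directions (43.0), and in SK-N-SH these counts were 29 (19.7), 38 (18.2) and 24 (37.9). Pearson's r of the effects across genes, which are not independent replicates, was 0.140 in IMR-32 (rho 0.169) and 0.0625 in SK-N-SH (rho 0.0829). Unchanged groups simulated from each line's own replicates against shared controls gave r of 0.376 and 0.397. The covariance was 0.0211 in IMR-32 against a simulated 0.00984 (0.00881 to 0.0117 from pairs of replicates), a difference of 0.0113. In SK-N-SH it was 0.0122 against 0.0165 (0.00914 to 0.0242), within that range (difference −0.00430). Simulated without pairing and with 1 spread for both lines the covariance was 0.0243, above both (differences −0.00321 and −0.0122), so the sign for IMR-32 depends on the simulation. The 3 DMSO arrays of a line were not split between the compounds, so part of the overlap may come from the shared controls. Without SK-N-SH WN replicate 3 the SK-N-SH r was −0.0657, and without SK-N-SH DMSO replicate 3 it was 0.246.

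Without treatment the lines differed in 6679 genes, 3502 higher and 3177 lower in SK-N-SH. The extracellular matrix gene TGFBI was undetected in IMR-32 and at least 422-fold higher in SK-N-SH (n = 3 per group, adjusted p = 1.71e-15), as were the smooth muscle gene TAGLN (233-fold), the transglutaminase TGM2 (178-fold) and the neuropeptide gene NPY (164-fold), each at least by that factor. MYC was undetected in IMR-32 and at least 39.5-fold higher in SK-N-SH. MYCN (−7.01 ± 0.36), ASS1, which encodes an enzyme of arginine synthesis (−6.53 ± 0.16), and the neuroendocrine factor INSM1 (−5.40 ± 0.29) were lower in SK-N-SH. On the IMR-32 DMSO arrays 4 to 39 probes were brighter than that of MYCN, so its size is not exact. The zinc finger gene ZIC2 was undetected in SK-N-SH and at least 76.3-fold lower. GPX4 was higher in SK-N-SH by 0.44 ± 0.14 and VIM by 1.21 ± 0.24, KEAP1 gave −0.69 ± 0.13, NFE2L2 −0.93 ± 0.21 and TFRC −0.73 ± 0.15, all lower in SK-N-SH, and HMOX1 at −0.73 ± 0.32 did not pass (adjusted p = 0.0643).

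The mesenchymal markers were higher in SK-N-SH in 26 and lower in 1 of 30 cases (same over the list alone, median 2.09, camera adjusted p = 1.27e-11, 0.293 with an estimated correlation), with PRRX1, undetected in IMR-32, at least 92.8-fold higher. All 6 measured genes of the metallothionein list were higher (same over the list alone, median 2.97, camera adjusted p = 0.000240, 0.293 with an estimated correlation, median 2.70 with bounds), led by MT2A (6.17 ± 0.21) and MT1E (4.49 ± 0.21). The adrenergic neuroblast markers had 8 higher and 5 lower of 26 (8 and 4 over the list alone, median 0.14, camera adjusted p = 0.545). STMN2 stood at 5.18 ± 0.41 and GATA2 at 4.46 ± 0.43. Cholesterol synthesis had 2 of 18 genes higher and 11 lower (same over the list alone, median −0.75, camera adjusted p = 0.0379, 0.698 with an estimated correlation). P53 targets had 10 of 21 genes higher and 1 lower (same over the list alone, median 0.51, camera adjusted p = 0.0190, 0.670 with an estimated correlation). DNA replication had 0 of 31 genes higher and 16 lower (same over the list alone, median −0.61, camera adjusted p = 0.000893, 0.698 with an estimated correlation). Mitosis had 0 of 35 genes higher and 5 lower (0 and 4 over the list alone, median −0.63, camera adjusted p = 0.0190, 0.856 with an estimated correlation). Ribosome biogenesis had 2 of 28 genes higher and 15 lower (same over the list alone, median −0.35, camera adjusted p = 0.0207, 0.384 with an estimated correlation). Proteasome had 1 of 27 genes higher and 12 lower (same over the list alone, median −0.37, camera adjusted p = 0.0130, 0.698 with an estimated correlation). None of the list calls of this comparison held with an estimated correlation. The arrays of the lines lay fully apart for 61.8% of genes, against 10% by chance.

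List median, mean and test differed in sign for lists without a call: with WN in IMR-32 for the unfolded protein response, ferroptosis, cholesterol, mitosis and adrenergic lists, with WN in SK-N-SH for mitosis and immune cells, between WA and WN in IMR-32 for metallothioneins, and between untreated lines for the heat shock, iron, ferroptosis and glutathione lists. The same held for the difference between lines in the WA effect for the glutathione and proteasome lists, and in the WN effect for the glutathione, mitosis, ribosome biogenesis and NF-kB lists. With undetected genes at their bounds the immune cell median went from −0.37 to −0.05 for WN in IMR-32, the mesenchymal median from 0.05 to 0.17, the NF-kB median from −0.13 to 0.00 and the Schwann cell median from −0.12 to −0.58. Between WA and WN in IMR-32 the Schwann cell median went from −0.06 to −0.63, the immune cell median from 0.46 to 0.00 and the metallothionein median from 0.03 to −0.09. Between the untreated lines the Schwann cell median went from 1.57 to 0.87. Smaller shifts turned the sign of medians near 0: with WN in IMR-32 metallothioneins went from −0.08 to 0.02 and heat shock from 0.01 to −0.05, and the signs of the unfolded protein response with WN in SK-N-SH and of heat shock between untreated lines turned as well. Medians not given moved by less than that of metallothioneins.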

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

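These results rest on a test of the difference between the lines, the effect in SK-N-SH minus that in IMR-32, in which 864 genes passed for WA. The tests of separate handling of the WN arrays, of the scaling between arrays and of SK-N-SH WA replicate 1, the scaling on detected probes, the replicate block within a line, the fit without the WN arrays, the deposited detection p-values, the agreement of other probes and the trend with level on median-scaled values were chosen only after the result was seen.

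By camera the median difference in the WA effect was 0.35 for NRF2 targets, 0.34 for the heat shock response, 0.27 for the unfolded protein response, 1.07 for the integrated stress response, −0.80 for DNA replication, −1.65 for mitosis, −0.86 for adrenergic and −0.45 for mesenchymal markers and 1.00 for Schwann cell markers, none of which held with an estimated correlation (adjusted p 0.344 to 0.518). Single genes with a positive difference were CEBPD (3.95 ± 0.87), LOX (3.27 ± 0.41), CA12 (2.98 ± 0.54), HTR3A (2.96 ± 0.23), VEGFD (2.91 ± 0.21), HSPA1A (2.82 ± 0.45), MIR221 (2.65 ± 0.41), MALL (2.60 ± 0.62), MIR21 (2.57 ± 0.37), SDCBP2 (2.55 ± 0.27), TXNRD1 (1.56 ± 0.29), GCLM (1.49 ± 0.35), CEBPB (2.53 ± 0.40), SLC7A5 (2.48 ± 0.28), STC2 (2.36 ± 0.47), CHAC1 (2.10 ± 0.38), SAT1 (2.24 ± 0.53) and SLC3A2 (1.57 ± 0.34). Single genes with a negative difference were AKR1C3 (−3.99 ± 0.53), TMEM100 (−3.92 ± 0.54), PPEF1 (−3.48 ± 0.64), AKR1C2 (−3.45 ± 0.44), FAM167A (−3.35 ± 0.69), IGFBP3 (−3.34 ± 0.91), NEFM (−3.32 ± 0.67), ANXA1 (−3.16 ± 0.60), LRRC17 (−3.12 ± 0.88), HEY1 (−3.03 ± 0.39) and MYCN (−2.97 ± 0.51). Of these, HSPA1A, MIR221, MALL, MIR21 and SDCBP2 were undetected on all IMR-32 DMSO and WA arrays, LOX on the IMR-32 WA arrays, STC2, ANXA1 and TMEM100 on the IMR-32 DMSO arrays, CHAC1 on the DMSO arrays of both lines and VEGFD, MIR21 and SDCBP2 on the SK-N-SH DMSO arrays. HTR3A was undetected on all SK-N-SH DMSO and WA arrays and MYCN on the SK-N-SH WA arrays, so these sizes depend on the detection floor. That of MYCN depends on the probe too. With single arrays left out, GCLM did not pass without IMR-32 DMSO replicate 2 (1.37). IGFBP3 did not pass without IMR-32 DMSO replicates 1 (−3.40), 2 (−3.46), 3 (−3.15), IMR-32 WA replicates 1 (−3.44), 2 (−3.13), 3 (−3.45), SK-N-SH WA replicate 2 (−3.05). LRRC17 did not pass without IMR-32 DMSO replicates 1 (−3.24), 2 (−3.36), 3 (−2.76), IMR-32 WA replicates 1 (−3.07), 2 (−2.89), SK-N-SH DMSO replicates 2 (−3.36), 3 (−2.38), SK-N-SH WA replicate 2 (−2.78). MALL did not pass without SK-N-SH DMSO replicate 2 (2.26) and SAT1 without replicate 1 (2.07). For WN the test of the difference gave medians of −0.45 for the metallothionein list, lost with an estimated correlation (adjusted p = 0.940), and 0.35 for immune cell markers, which held (0.0206).

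The difference in the WA effect between the lines was not bound to dim genes, since 5.83% of the genes detected on all 12 DMSO and WA arrays passed. The lower count of both other scalings was 541, and without SK-N-SH WA replicate 1 the count was 2236, which argues against the scaling or that array as the whole cause. Of 100 regroupings of the arrays in the fit of 12 arrays 1 gave as many genes as the real grouping (558), itself, and the highest of the others gave 30. Regrouping mixes WA with DMSO arrays, which leaves few calls whether or not the lines differ. For WN the real grouping gave 0 genes in limma (659 at an unadjusted p under 0.05), so all 100 regroupings gave at least as many. Neither decided whether the lines differ. A difference between the lines in their response to WA may be the cause, a hypothesis found and tested on the same arrays.

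The WN effects of both lines went the same way in all 104 genes called in both, and WN arrays of both lines were dim. Removing a trend with signal level left the correlation of the effects across genes at 0.589, which decided nothing, since the trend held 0.459% and 0.269% of their variance. On values scaled to the median it held 23.2% and 10.2%, and its removal moved r from 0.594 to 0.531 (0.419 to 0.556 with single arrays left out), which argues against such a trend as the whole cause. Other probes of the called genes moved the same way in 73.2% of 314 cases (interval 68.0 to 78.1), 75.9% in IMR-32 and 67.0% (56.6 to 76.4) in SK-N-SH. For WA calls as large as the WN calls of the line it was 89.6% and 85.5%, so differences between probes stay open. Separate handling of the WN arrays may be the cause and cannot be told apart from an effect of WN, since 0 arrays lay in the highest-signal range of the other set. An effect of WN itself stays open too, untested beyond these values.

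On SK-N-SH WA replicate 1 the 4878 genes called from the other arrays moved with a slope of 0.490, whereas those of the DMSO arrays were −0.0963, −0.0641 and 0.160, which argues against an exchange with a DMSO array. Genes that part the untreated lines had slopes of 1.02 there and 0.985 and 1.01 on replicates 2 and 3. Quantile normalization evens out compression, so this cannot decide on compressed signal. Untreated RNA mixed in would give raised and lowered genes a like share of the linear effect, but raised genes reached 0.438 (0.407 to 0.458) and lowered genes 0.579 (0.556 to 0.594), a difference of −0.141. A weaker or later response of that culture may be the cause, and the labels name nothing that sets it apart, so no biological explanation was tested.

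With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Only the real split, 1 of 10 in each comparison, gave as many genes, and the highest other split gave 0 for WA in IMR-32 (real 1883), 2 for WN in IMR-32 (595), 0 for WA against WN in IMR-32 (3081), 594 for WA in SK-N-SH (4134), 581 for WA against WN in SK-N-SH (4969), 0 for WN in SK-N-SH (238) and 0 for the untreated lines (6679). For WA in SK-N-SH the highest split that parted all 3 replicate pairs gave 0 genes in limma and the highest of the rest 594, and for WN in IMR-32 these were 0 and 2. The replicate number within each line as a block gave 4954 and 987 genes in these comparisons.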

How the results depend on the processing

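The replicate block within a line, the scaling on detected probes, the deposited detection p-values and the fit without the WN arrays were chosen only after the result was seen. Of 8879 alternatives to 432 fold changes of named genes, each in 1 comparison, 399 of them past the threshold, 8200 kept direction and side of the threshold, 610 no longer passed, 22 passed in addition and 47 reversed, 0 of these in a gene past the threshold. The cause was not tested for any value given here, except that stricter thresholds and fewer arrays allow fewer calls. Other alternatives of the counts, correlations and the lists of NRF2 targets, heat shock response, integrated stress response, iron handling and ferroptosis regulators stayed within 1.5-fold or kept direction and side of the threshold. Chip as a block was not run, because the files name no chip. Dim probes near background limit what fold sizes can be measured.

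The number of genes past the threshold, in the fit of all arrays, was 1883 (IMR-32 WA), 595 (IMR-32 WN), 3081 (IMR-32 WA against WN), 4134 (SK-N-SH WA), 238 (SK-N-SH WN), 4969 (SK-N-SH WA against WN), 864 (WA difference between lines), 0 (WN difference between lines, in limma, 478 at an unadjusted p under 0.05), 6679 (untreated lines), 978 (WA overlap). With median scaling in place of quantile normalization the number of genes was 1230 (IMR-32 WA), 3090 (IMR-32 WN), 4770 (IMR-32 WA against WN), 558 (SK-N-SH WN), 541 (WA difference between lines), 1 (WN difference between lines), 546 (WA overlap). In that setting r was 0.188 (IMR-32), 0.107 (SK-N-SH). There the list median was 0.20 (ferroptosis regulators WA difference between lines, now past the threshold). There these genes, not past the threshold, reversed: GPX4 IMR-32 WA −0.0810, KEAP1 IMR-32 WN −0.29, NFE2L2 IMR-32 WN −0.27, TFRC IMR-32 WN −0.39, MYCN IMR-32 WN −0.70, VIM IMR-32 WN −0.34, HMOX1 SK-N-SH WN −0.0634, NFE2L2 SK-N-SH WN −0.28, GPX4 SK-N-SH WN −0.30, MYCN SK-N-SH WN −0.14, VIM SK-N-SH WN −0.44. With array weights the number of genes was 3908 (IMR-32 WA), 3151 (IMR-32 WN), 5678 (IMR-32 WA against WN), 1494 (SK-N-SH WN), 2374 (WA difference between lines), 5 (WN difference between lines), 1791 (WA overlap). There r was 0.127 (IMR-32), 0.0749 (SK-N-SH). There the list median, now past the threshold, was 0.29 (iron handling SK-N-SH WA), 0.33 (ferroptosis regulators WA difference between lines). There these genes, not past the threshold, reversed: ACSL4 IMR-32 WA −0.0297, HMOX1 IMR-32 WN 0.14, GPX4 IMR-32 WN 0.0377, NFE2L2 SK-N-SH WN −0.0509. At an adjusted p under 0.01 the count was 888 (IMR-32 WA), 62 (IMR-32 WN), 1614 (IMR-32 WA against WN), 2508 (SK-N-SH WA), 4 (SK-N-SH WN), 3205 (SK-N-SH WA against WN), 230 (WA difference between lines), 401 (WA overlap). With at least a 2-fold change asked as well the number of genes was 492 (IMR-32 WA), 48 (IMR-32 WN), 691 (IMR-32 WA against WN), 1251 (SK-N-SH WA), 52 (SK-N-SH WN), 1536 (SK-N-SH WA against WN), 3001 (untreated lines). Without background correction the count was 921 (IMR-32 WN), 423 (SK-N-SH WN). With every probe tested the count was 1016 (IMR-32 WN), 4792 (IMR-32 WA against WN), 10451 (untreated lines). With the deposited series matrix values the count was 918 (IMR-32 WN), 423 (SK-N-SH WN). With the replicate number within each line as a block the count was 987 (IMR-32 WN), 495 (SK-N-SH WN), 1751 (WA difference between lines). With only the groups compared in the fit the number of genes was 1714 (SK-N-SH WA), 0 (SK-N-SH WN, in limma, 1948 at an unadjusted p under 0.05), 3169 (SK-N-SH WA against WN), 558 (WA difference between lines). Without the 6 WN arrays the count was 551 (WA difference between lines). With scaling on the median of probes detected on all arrays r was 0.188 (IMR-32), 0.107 (SK-N-SH). There the list median was 0.27 (ferroptosis regulators WA difference between lines, now past the threshold). There these genes, not past the threshold, reversed: GPX4 IMR-32 WA −0.12, ACSL4 IMR-32 WA −0.00490, HMOX1 IMR-32 WN 0.11, SLC7A11 IMR-32 WN 0.45, MYCN IMR-32 WN −0.20, GPX4 SK-N-SH WN −0.0188, VIM SK-N-SH WN −0.16. Without a detection filter r was 0.160 (IMR-32), 0.0773 (SK-N-SH). There the list median, now past the threshold, was 0.11 (iron handling IMR-32 WA), 0.16 (iron handling SK-N-SH WA). With the mean of all probes of a gene r was 0.0514 (SK-N-SH). With an estimated correlation in camera, where the list was no longer past the threshold, the list median was 0.39 (heat shock response IMR-32 WA), 0.34 (integrated stress response IMR-32 WA), 0.16 (ferroptosis regulators IMR-32 WA), 0.75 (heat shock response SK-N-SH WA), 1.79 (integrated stress response SK-N-SH WA), 0.33 (ferroptosis regulators SK-N-SH WA), 0.35 (NRF2 targets WA difference between lines), 0.34 (heat shock response WA difference between lines), 1.07 (integrated stress response WA difference between lines). With the deposited detection p-values the list median was 0.21 (iron handling SK-N-SH WA, now past the threshold). With the replicate number shared by both lines as a block the list median was 0.24 (ferroptosis regulators WA difference between lines, now past the threshold).

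With each array left out in turn, which leaves 2 arrays in a group, the number of genes lay between 1123 and 1591 (IMR-32 WA), 125 and 518 (IMR-32 WN), 2006 and 2659 (IMR-32 WA against WN), 1 and 152 (SK-N-SH WN), 519 and 2236 (WA difference between lines), 0 and 2 (WN difference between lines), 589 and 1184 (WA overlap). Pearson's r lay between 0.117 and 0.203 (IMR-32), −0.0657 and 0.246 (SK-N-SH). List medians lay between 0.19 and 0.31 (iron handling SK-N-SH WA), 0.17 and 0.34 (ferroptosis regulators WA difference between lines), 0.0268 and 0.0930 (iron handling IMR-32 WA), 0.20 and 0.44 (ferroptosis regulators SK-N-SH WA), 0.23 and 0.55 (NRF2 targets WA difference between lines), 0.14 and 0.43 (heat shock response WA difference between lines), −0.0319 and 0.19 (iron handling WA difference between lines). Genes not past the threshold whose direction reversed in this way lay between −0.0605 and 0.12 (GPX4 IMR-32 WA), −0.14 and 0.17 (ACSL4 IMR-32 WA), −0.0419 and 0.0469 (TFRC IMR-32 WA), −0.23 and 0.18 (HMOX1 IMR-32 WN), −0.12 and 0.0690 (GPX4 IMR-32 WN), −0.22 and 0.0205 (SLC7A11 IMR-32 WN), −0.0457 and 0.22 (VIM SK-N-SH WA), −0.14 and 0.19 (HMOX1 SK-N-SH WN), −0.19 and 0.0332 (KEAP1 SK-N-SH WN), −0.0693 and 0.0769 (NFE2L2 SK-N-SH WN), −0.0989 and 0.0136 (TFRC SK-N-SH WN), −0.42 and 0.56 (MYCN SK-N-SH WN).

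The replicate number within each line as a block also brought past the threshold VIM with WA in IMR-32 (0.50), ACSL4 with WN in IMR-32 (−0.79) and SK-N-SH (−0.66) and TFRC with WA in SK-N-SH (0.38). It changed the calls of the mesenchymal list with WA in IMR-32 (adjusted p = 0.0295) and of ribosome biogenesis between WA and WN in SK-N-SH (0.0690). It changed no other call of a gene followed throughout or of a list.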

Other observations

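Among the 44 genes that WA moved in opposite directions in the lines were S100A4, which encodes a calcium-binding protein known from metastasis, at 1.58 ± 0.20 in IMR-32 and −1.21 ± 0.20 in SK-N-SH (difference −2.79, adjusted p = 7.30e-05). PAQR8, a membrane progesterone receptor gene, stood at 1.54 ± 0.18 in IMR-32 and −1.03 ± 0.18 in SK-N-SH (difference −2.57, adjusted p = 6.16e-05). The nuclear lamina gene LMNA changed by 0.69 ± 0.15 in IMR-32 and −0.80 ± 0.15 in SK-N-SH (difference −1.48, adjusted p = 0.00101). In the other direction MTHFD1L, a mitochondrial enzyme of folate metabolism, changed by −0.94 ± 0.15 in IMR-32 and 0.89 ± 0.15 in SK-N-SH (difference 1.83, adjusted p = 0.000152). These 4 genes were chosen after their values were seen, each with 3 arrays per group, and each kept both calls in limma with any single array left out.

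Genes that WN moved alike in IMR-32 and SK-N-SH (values in this order), all chosen after their values were seen, were P2RY11 (−0.84 and −1.09), SNORD104 (−1.23 and −1.07) and RPL21 (−1.18 and −1.04). Others were the cap methyltransferase gene TGS1 (−1.29 and −0.97, dimmer probe −0.091 and −0.364), ZNF573 (0.98 and 1.13) and the prolyl isomerase gene PPIL1 (1.04 and 0.87). Without SK-N-SH WN replicate 1 the count in that line was 1, and of these genes P2RY11 kept its call there with every array left out in turn. The arrays of both WN groups were dim, and whether these changes come from WN or from the handling of its arrays was not separable.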
